A study of Mus musculus with 4 samples.

How the data were processed

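Single-cell RNA was measured in cells sorted by green fluorescent protein (GFP) from the pancreas of 1 Rag2-/- MIP-GFP mouse, in which the mouse insulin promoter drives GFP. The pancreas was taken 2 months after AdPNM, an adenovirus that carries the transcription factors Pdx1, Neurog3 and MafA, had been injected backwards through the common bile duct. Per the labels' protocols, libraries were made with the 10x Genomics 3′ v2 kit and sequenced on a NextSeq 500 with paired reads of 75 bases. Insulin-positive duct cells and β-cells were pooled into 1 sample before the library was made. The series lists 4 samples with the same description. All barcodes of the matrix carry the same suffix and none maps to a sample, so the matrix was treated as 1 library from 1 animal.

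The deposited matrix holds whole-number UMI counts per feature and cell, with no normalization, and the genes and barcodes come in separate lists. Per the submitters' processing notes, Cell Ranger 2.0 and the builds GRCm38 and mm10 were used; aligner settings and cell-calling thresholds were not given in the sources used here. The feature list holds 51917 entries. Of these, 51912 have an Ensembl identifier and 5 are added sequences: ad5_F, ad5-rc, adeno-Mafa_3Prime, endo-Mafa_3Prime and egfp. By their names, the first 3 were taken as vector features, and what part of the vector each covers was not given in the sources used here. Coordinates of genes come from GENCODE M21 (GRCm38), which holds 51719 of the Ensembl identifiers. Reads shared by Ins1 and Ins2, by the class I genes H2-K1, H2-D1 and H2-Q7, or by the Mafa gene and the vector's MafA may be split between features in a way that the counts cannot resolve.

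Cells were kept with at least 200 genes and under 20% of UMIs from mitochondrial genes, which removed 0 of 501 cells. The library held 17088264 UMIs, with 6433 to 89473 per cell (median 34697). The smallest rate that a count of 0 excludes was set at 3 counts, or 0.658 CPM (counts per 1000000) over all vector-positive cells, 0.239 CPM over vector-negative cells and 7.70 CPM over cells with at least 3 vector UMIs.

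A cell with at least 1 UMI of any vector feature was called vector-positive, and all others vector-negative. UMIs were summed over the cells of a class and expressed as CPM over all features except the vector. Levels of single clusters are CPM over all features, the vector included, and the few cluster ratios leave it out. Intervals are exact 95% Poisson intervals for CPM, exact conditional (binomial) intervals for ratios and Clopper-Pearson intervals for shares of cells. They cover counting error only. With 1 animal there is no replicate, so no test between classes was made and no p-value is given. Log2 ratios add 0.5 UMIs to each sum. For each of 13 gene lists the median log2 ratio was taken over members with at least 20 UMIs, and placed among 10000 random lists of the same size whose members were matched on UMI count within 100 ranks. These percentiles describe this library.

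Cells were clustered without the vector features, with scanpy 1.11.5 and igraph 0.11.9. Counts were scaled to 10000 per cell and log-transformed, genes were scaled to unit variance, and 2000 variable genes, 20 principal components, 15 neighbours and a Leiden resolution of 0.5 were used. Leading genes of a cluster were the 10 with the largest ratio of CPM to all other cells, with 5 CPM added to both, among genes with a UMI in at least 25% of its cells. A cluster was to be named from 12 marker lists, but each of the 3 clusters failed a condition for a name, so they go by number. Clusters of other cell types were to be left out of the class comparison. No cluster was named as one, so all 501 cells stayed in it. Shares of cells with a UMI were compared after thinning each cell without replacement to 9812 UMIs, the 10th percentile of depth. This left out 16 vector-positive and 34 vector-negative cells. Doublets were not removed, and leaving out those called by Scrublet was an alternative. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.

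Named genes follow rules set before the data were examined. They are Ins1, Ins2, Iapp, Pdx1, Neurog3, Mafa, Gcg, Sst, Ppy, Krt19, Sox9, Spp1 and the vector features, and the 12 genes with the highest and the 12 with the lowest ratio. The latter needed at least 50 UMIs, a UMI in at least 10% of cells of the higher class and at most 20% of that class's UMIs from 1 cell, and clones, mitochondrial and ribosomal genes were left out. In each list, up to 4 members with the most UMIs were named, together with members of at least 20 UMIs and a ratio above 2 or under 0.5. A few genes that met these rules are left out of the text and of the counts over named genes. The classes, gene lists, marker lists, clustering and alternative settings listed at the end were also set before the data were examined. Chosen after seeing the data were the class with at least 3 vector UMIs, the comparisons within or without single clusters, the genes egfp and endo-Mafa_3Prime, the removal of 3 cells, cluster ratios with insulin out of the total and hormones without their top cells. These 3 cells lie in cluster 2 and hold at least 60% of the duct, endothelial or mesenchymal markers. Applied to all cells, the same limit also caught deep cells of cluster 0 by duct markers, and it was then restricted to cluster 2.

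The class comparison was tested on simulated counts drawn from the real means, in which 50 of 9789 genes were changed by each of 4 known folds. Each class was drawn as 1 sum of UMIs without single cells, so the simulation cannot show how spread between cells or clusters acts on the ratios. The median recovered ratio was 0.234, 0.505, 1.98 and 3.95 for folds of 0.25, 0.5, 2 and 4. A list of 12 genes planted at 2-fold fell at the 100th percentile, and 8% of random lists with no effect fell outside the 95% range. Alternative settings fixed in advance changed the vector threshold, the depth of vector-negative cells, the cell filter, the CPM total, the weight of each cell, doublets, the UMI minimum of list members, the clustering and the thinning.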

Results

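The data are UMI counts of 501 GFP-sorted pancreatic cells from 1 mouse, 2 months after a vector carrying Pdx1, Neurog3 and MafA had been delivered to its pancreatic ducts. The sort pooled insulin-positive duct cells with β-cells, and vector sequence in a cell was meant to tell the 2 kinds apart. The library held 17088264 UMIs, of which 57.9% came from the insulin genes Ins1 and Ins2. A cell held a median of 34697 UMIs and 4226 genes, and at most 3.77% of its UMIs were mitochondrial. There are no replicates, and all intervals below cover counting error only.

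The first question was how many cells carried vector RNA. At least 1 vector UMI was found in 134 of 501 cells, or 26.7% (22.9 to 30.9), at least 2 in 48 cells (9.58%, 7.15 to 12.5) and at least 3 in 21 cells (4.19%, 2.61 to 6.34). The feature ad5_F was seen in 80 cells, adeno-Mafa_3Prime in 69 and ad5-rc in 18. The share depended on depth: among the 451 cells thinned to 9812 UMIs it was 11.8% (8.93 to 15.1). UMIs of egfp, the reporter used for the sort, were counted in all 501 cells. Per 100 insulin UMIs there were 2.66 in 28 Gcg-rich cells, 2.99 in cluster 0 and 6.60 in 70 cells of cluster 2. The Gcg-rich cells thus held egfp in about the ratio of cluster 0, so an egfp UMI alone does not show that a cell made it.

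Clustering without the vector features set apart a group of 73 cells, cluster 2, that held most of the vector RNA. Vector UMIs were found in 48 of its 73 cells (65.8%, 53.7 to 76.5), in 79 of the 356 cells of cluster 0 (22.2%, 17.98 to 26.9) and in 7 of the 72 cells of cluster 1 (9.72%, 3.999 to 19.0). Cells of cluster 2 were also the shallowest, with a median of 11259 UMIs against 41398 in cluster 0 and 18938 in cluster 1. Thinning left out 23 cells of cluster 2, 10 of cluster 0 and 17 of cluster 1. The shares were then 64.0% (49.2 to 77.1), 5.49% (3.34 to 8.44) and 3.64% (0.443 to 12.5) for clusters 2, 0 and 1. Of the 21 cells with at least 3 vector UMIs, 20 were in cluster 2 and 1 in cluster 0. Vector UMIs made up 186 CPM (160 to 215) of cluster 2, 6.46 CPM (5.22 to 7.91) of cluster 0 and 5.16 CPM (2.23 to 10.2) of cluster 1.

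**Figure D1:**
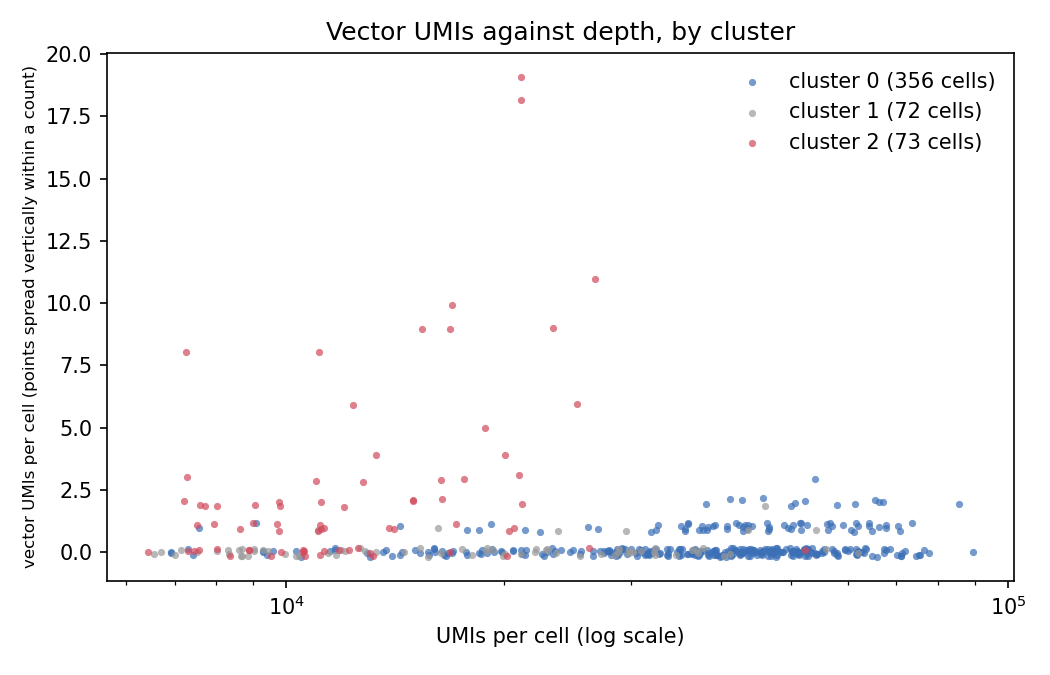
Vector UMIs per cell (vertical axis, with points spread within a count) against total UMIs per cell (horizontal log axis), 1 point per cell, coloured by cluster. Of the 21 cells with at least 3 vector UMIs, 20 belong to cluster 2, whose median depth is 11259 UMIs.

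The clusters differed in the hormone RNA that they held. Cluster 0 was led by the haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs, with 86.7% of its Hba-a1 UMIs in 1 cell, followed by Plut, Car10 and Cox6a2. It had the highest Ins1 (226302 CPM) and Ins2 (386654 CPM). Cluster 1 was led by Gcg, Sst, Ppy and Pyy, the hormones of the other islet cell types, with Gcg at 32820 CPM (32536 to 33107). The Gcg RNA was concentrated: the median cell of cluster 1 held 852 CPM, near the 806 CPM of cluster 0. At a finer resolution of 1.0, 28 cells stood apart with Gcg at 174679 CPM, and 44 others had Ppy at 5874 CPM with 81.8% of these UMIs in 1 cell. The median of these 44 cells held 316 CPM of Ppy. They were rich in insulin RNA, with Ins1 at 199910 CPM and Ins2 at 310363 CPM. Cluster 2 was led by Gip, which encodes an incretin hormone, and also by Gal, 2810474O19Rik, Cd9, B2m, Ambp, Pigr, Onecut2 and adeno-Mafa_3Prime. Gip stood at 14594 CPM there (14358 to 14834), but 13 cells held 96.3% of these UMIs, and 1 cell held 84.6% of the Gal UMIs. Erythroid genes among its leading genes kept cluster 0 from a β-cell name, markers of several hormones did so for cluster 1, and cluster 2 had a median depth under the minimum set for a name (11566 UMIs) and none of the markers among its leading genes.

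Cells of cluster 2 contained insulin RNA. Ins1 and Ins2 took a median of 31.9% of UMIs in 70 of its cells (range 6.30 to 56.3) and 61.6% in cluster 0. The other 3 cells, all vector-negative, carried markers of duct, endothelial or mesenchymal cells. The duct-marker cell held 54 of the 55 Krt19 UMIs of cluster 2. egfp was at 20650 CPM in cluster 2 and 18323 CPM in cluster 0. CPM levels and fold values of cluster 2 in this paragraph include the 3 cells with other markers. Levels between these clusters depend on the total, since insulin takes up more of it in cluster 0. With insulin, Iapp and mitochondrial genes out of the total, a scale tried after the data were seen, egfp was lower in cluster 2, at 0.578-fold (0.570 to 0.586). Per 100 insulin UMIs, egfp was higher in the 70 cells of cluster 2, at 6.60 against 2.99 in cluster 0. Transcripts of the maturity genes Ucn3 and G6pc2 were lower in cluster 2, at 112 CPM (91.8 to 134) against 242 CPM (235 to 251) for Ucn3 and 347 CPM (311 to 386) against 739 CPM (725 to 753) for G6pc2. Slc2a2, the glucose transporter of the mouse β-cell, was at 131 CPM (109 to 155) and 143 CPM (137 to 149), within counting error, but at 0.470-fold (0.391 to 0.562) with insulin out of the total, where Ucn3 was at 0.236-fold and G6pc2 at 0.241-fold.

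The vector's 3 factors were not equally visible. Counts of the Mafa gene (ENSMUSG00000047591, chromosome 15, 75745490 to 75748228, GRCm38) were 61.3 CPM (46.9 to 78.8) in cluster 2 and 0.688 CPM (0.330 to 1.26) in cluster 0. The feature endo-Mafa_3Prime, by its name alone the endogenous 3′ sequence, was at 3.02 CPM (0.622 to 8.82) in cluster 2 and 7.29 CPM (5.97 to 8.82) in cluster 0, with overlapping intervals. Pdx1 was at 126 CPM (105 to 150) and 59.3 CPM (55.4 to 63.4). With insulin, Iapp and mitochondrial genes out of the total, cluster 2 stood at 45.8-fold (23.3 to 100.2) of cluster 0 for Mafa, 0.212-fold (0.0431 to 0.638) for endo-Mafa_3Prime and 1.09-fold (0.895 to 1.31) for Pdx1, the last within counting error. Levels and folds of cluster 2 here include its 3 cells with markers of other types, which may lower or raise them. Neurog3, the driver of endocrine commitment in the embryo, gave 1 UMI in cluster 2, 5 in cluster 0 and 15 in cluster 1. These are 1.01 CPM (0.0255 to 5.60), 0.344 CPM (0.112 to 0.802) and 9.68 CPM (5.42 to 16.0). The vector feature adeno-Mafa_3Prime was at 88.5 CPM (71.0 to 109) in cluster 2 and 2.48 CPM (1.73 to 3.43) in cluster 0. No added sequence is named for the vector's Pdx1 or Neurog3, so these counts cannot show whether the vector's copies were transcribed.

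The second comparison set the 134 vector-positive cells against the 367 vector-negative cells, the contrast by which the labels separate converted duct cells from β-cells. Insulin RNA was close between the classes: Ins1 and Ins2 made up 56.6% of UMIs in vector-positive and 58.3% in vector-negative cells, a ratio of 0.971. The amyloid gene Iapp had a ratio of 0.898 (0.893 to 0.902) and Pdx1 of 1.22 (1.07 to 1.39). egfp was higher, at 21004 against 16729 CPM, a ratio of 1.26 (1.25 to 1.27). Most vector-positive cells (79 of 134) belonged to cluster 0, and the values depended on how many vector UMIs were asked for. In cells with at least 3, insulin made up 39.3% of UMIs (ratio 0.674), Iapp had a ratio of 0.516 (0.505 to 0.527) and Pdx1 of 2.58 (1.95 to 3.35). Because insulin took up less of the total, the median ratio over all genes was 1.09 with at least 1 vector UMI and 1.69 with at least 3, and 1.02 and 1.07 with insulin, Iapp and mitochondrial genes out of the total.

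**Figure D2:**
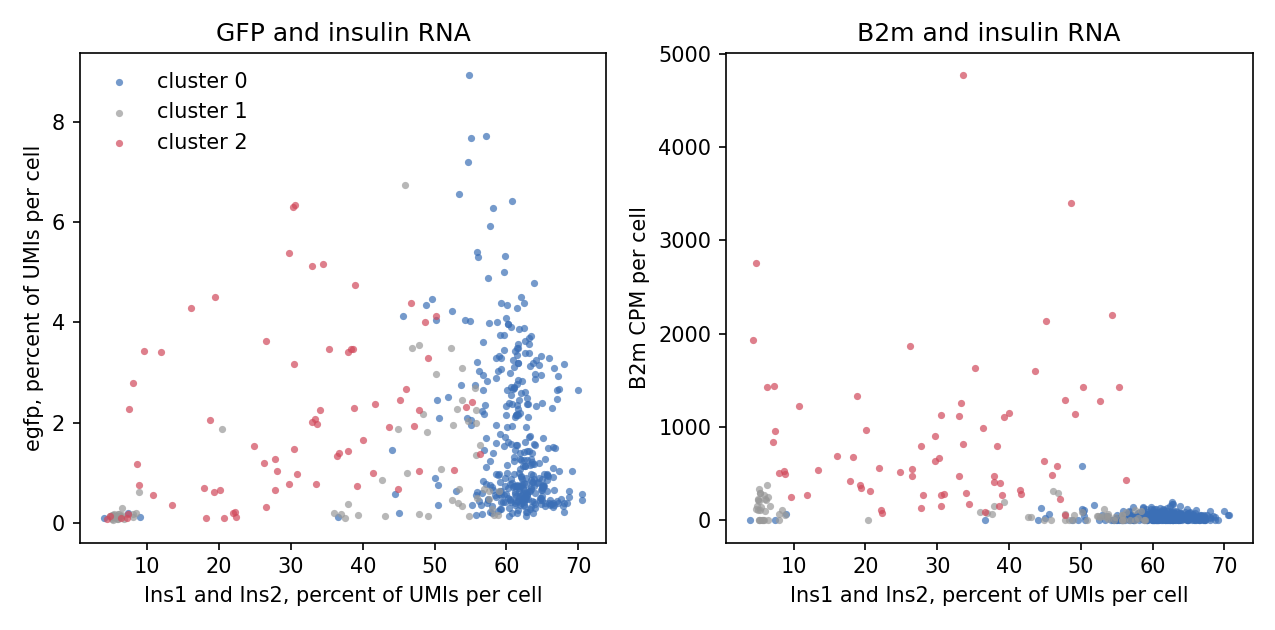
Percent of UMIs from egfp (left) and B2m CPM (right) per cell, each against the percent of UMIs from Ins1 and Ins2, 1 point per cell, coloured by cluster. Cells of cluster 2 spread over insulin shares of 4.35% to 56.3% and hold the highest B2m values, while the median of cluster 0 is 61.6%.

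Mafa had the highest ratio, with 14.3 against 0.638 CPM, or 22.3-fold (10.7 to 53.9). This partly restates how the classes were made, since its feature may take up reads of the vector's MafA. Other genes with high ratios were the homeobox genes Nkx6-2 (ratio 6.32, 4.06 to 10.1), Barhl1 (4.95, 3.11 to 8.01) and Onecut2 (3.91, 2.75 to 5.58), the last a liver and endoderm factor. Also in this group were Endou (4.74), Rprml (4.64), the translation factor Eef1a2 (4.63), the class I gene H2-Q7 (3.74), the chloride channel gene Clic6 (3.67), the interferon regulator Irf7 (3.63) and the tetraspanin Cd9 (3.34). With at least 3 vector UMIs the ratio was 177 (82.3 to 435) for Mafa, 26.8 (15.1 to 47.1) for Nkx6-2 and 19.2 (12.2 to 29.8) for Onecut2. Within cluster 0 alone, Nkx6-2 had a ratio of 1.78, Onecut2 of 1.32 and Cd9 of 0.685. Endou and Rprml also reversed there, with log2 ratios of -0.27 and -0.20. Within cluster 2, Onecut2 and Clic6 reversed, at -0.13 and -0.15. The other genes of this paragraph were not among the reversed ones in either cluster.

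Islet hormones other than insulin were lower in vector-positive cells. Gcg was at 1691 against 4465 CPM (ratio 0.379, 0.370 to 0.388), Sst at 862 against 2137 CPM (0.404, 0.390 to 0.417), Ppy at 519 against 1336 CPM (0.389, 0.372 to 0.406) and Pyy had a ratio of 0.480 (0.460 to 0.501). All 7 measured members of the hormone list were lower, with a median log2 ratio of -1.06. A single cell held 49.7% of the Gcg UMIs of the vector-positive class, and another 36.3% of the Ppy UMIs of the vector-negative class. Without the cell that held the most in each class, the ratios were 0.211 for Gcg, 0.297 for Sst, 0.491 for Ppy and 0.459 for Pyy. The difference lay in cluster 1: without it Gcg had a ratio of 1.06, Sst of 1.67 and Ppy of 0.918. It also depended on depth. Against vector-negative cells from the median depth up, log2 ratios reversed to 1.04 for Gcg, 0.49 for Sst and 0.093 for Ppy. The list median was then -0.093. Sst in cells with at least 3 vector UMIs had a ratio of 1.74 with 90.0% of its UMIs in 1 cell. Other genes with the lowest ratios were Tepsin (0.292), Plppr4 (0.306), Polr3a (0.332), the δ-cell factor Hhex (0.344), Gemin8 (0.401), Sec22c (0.401), Msln (0.409), Zfp442 (0.418) and Klhdc9 (0.428), all of them under 6 CPM in both classes.

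Antigen presentation and interferon-responsive genes were higher in vector-positive cells. Of 16 measured members 13 were higher, with a median log2 ratio of 0.84, above all 10000 matched random lists. B2m (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), the light chain of class I molecules, was at 179 against 68.2 CPM, a ratio of 2.62 (2.38 to 2.89). H2-D1 had a ratio of 1.77 (1.62 to 1.92), H2-K1 of 1.41 (1.30 to 1.52) and Ifi27 of 2.12 (1.90 to 2.36). The peptide transporter Tap1 (2.64), Ifit1 (2.16) and Oasl2 (2.09) were also higher, and Ifitm3 was lower (0.468), a direction that rested on the 3 cells with other markers (1.03 without them). With at least 3 vector UMIs the list median was 2.73, or 2.07 with insulin, Iapp and mitochondrial genes out of the total. On the first scale 15 of 16 members were higher and B2m was at 13.3-fold (11.7 to 15.1). Within cluster 0 the list median was 0.23. Within cluster 2 it was 0.28 without the 3 cells and -0.54 with them.

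Genes of endocrine progenitors, of the p53 response and of the immediate early response were mostly higher in vector-positive cells, by differences that rested on cluster 2. In the endocrine progenitor list 6 of 7 measured members were higher (median log2 ratio 0.59, 99.4th percentile), among them Sox4 (1.86, 1.49 to 2.32), Sox11 (3.67, 1.91 to 7.17), Hes6 (1.57, 1.30 to 1.89) and Btbd17 (1.37, 1.08 to 1.72). Fev was at 1.49 (0.887 to 2.45), within counting error, and Neurog3 gave 1 against 20 UMIs. The p53 and apoptosis list had 10 of 12 members higher (0.29, 95.8th percentile), with the cell cycle inhibitor Cdkn1a at 3.19 (2.64 to 3.86), Gadd45a at 2.13 (1.64 to 2.75) and Cdkn2a at 2.12 (0.830 to 5.22). Bax (1.13), Ccng1 (1.32) and Mdm2 (1.10) stood closer to 1. Immediate early genes, which dissociation of tissue can raise, had 8 of 11 members higher (0.27, 99.3rd percentile), with Jund at 1.29 (1.19 to 1.39), Junb at 1.30 (1.12 to 1.496), Fos at 1.21 (1.08 to 1.35) and Btg2 at 1.13 (0.993 to 1.29). With at least 3 vector UMIs the medians of these lists were 2.08, 1.75 and 1.56, or 1.42, 1.09 and 0.90 with insulin, Iapp and mitochondrial genes out of the total. With cluster 2 left out they were below 0, at -0.23, -0.14 and -0.26.

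Keratin and duct genes gave a mixed picture. In the duct list 12 of 15 measured members were higher, with a median log2 ratio of 0.15 (72.4th percentile) and of 1.36 (99.9th percentile) with at least 3 vector UMIs. The first was -0.14 with cluster 2 left out and -0.57 within cluster 2 (-0.017 there without 3 cells described above), and the second 0.70 with insulin, Iapp and mitochondrial genes out of the total. On that last scale, cells with at least 3 vector UMIs had ratios of 2.24 (1.80 to 2.76) for Krt8, 1.75 (1.34 to 2.25) for Krt7, 3.53 (2.99 to 4.14) for Clu, 1.59 (1.33 to 1.89) for Epcam and 1.92 (1.11 to 3.12) for Spp1. Krt18 was at 1.17 (0.916 to 1.48), within counting error. The duct keratin gene Krt7 was abundant in both classes, at 68.2 and 62.2 CPM, while Krt19 and Sox9 were scarce. Krt19 (ENSMUSG00000020911, chromosome 11, 100140810 to 100148665) was at 0.878 against 5.83 CPM, a ratio of 0.151 (0.0400 to 0.403) that became 0.575 (0.142 to 1.73) without the 3 cells, and Anxa2, at 0.373 (0.154 to 0.784), became 1.82 (0.646 to 4.85). Sox9 gave 0 UMIs in vector-positive cells, which allows up to 0.658 CPM, against 11 UMIs (0.878 CPM) in vector-negative cells. The interval of its ratio, 0 to 1.10, was within counting error of 1. Krt19 gave 0 UMIs in cells with at least 3 vector UMIs, which allows 7.70 CPM, so a difference from the 5.83 CPM of vector-negative cells was not detectable at this depth.

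Lists of β-cell function had medians near 0 between the classes. In the list of β-cell transcription factors 10 of 12 members were higher, with a median log2 ratio of 0.15 (82.6th percentile); Pax6 (1.06), Nkx6-1 (1.10), Neurod1 (1.13) and Insm1 (1.20) were near 1. Glucose sensing and secretion genes had 9 of 15 members higher and a median of 0.02, with G6pc2 at 1.06, Ppp1r1a at 1.04, Ucn3 at 1.02 and the zinc transporter Slc30a8 at 0.838 (0.767 to 0.915). With at least 3 vector UMIs, Ucn3 (0.733, 0.563 to 0.938), G6pc2 (0.652, 0.557 to 0.758) and Slc30a8 (0.632, 0.456 to 0.854) were lower. Neurod1 was at 2.00 (1.62 to 2.44), an interval that holds the median ratio of 1.69 over all genes in that class. In that class the medians of the glucose sensing, prohormone and ER stress lists were 0.20, 0.23 and -0.13, at the 0.70th, 15.6th and 0.010th percentile of matched lists. With insulin, Iapp and mitochondrial genes out of the total they were -0.46, -0.43 and -0.79. The prohormone list split 9 higher to 7 lower with a median of 0.04, with Chgb at 1.25 and Chga at 0.919, Pcsk2 at 1.03 and Pcsk1n at 0.878. ER stress genes split 9 to 9, with a median of 0.01, Hspa5 at 1.08, Hsp90b1 at 1.19, Calr at 1.06 and Manf at 1.02. Mitochondrial genes split 7 to 6 around 0.02, with mt-Cytb at 0.993, mt-Nd1 at 1.01, mt-Nd4 at 0.948 and mt-Nd2 at 0.994.

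**Figure D3:**
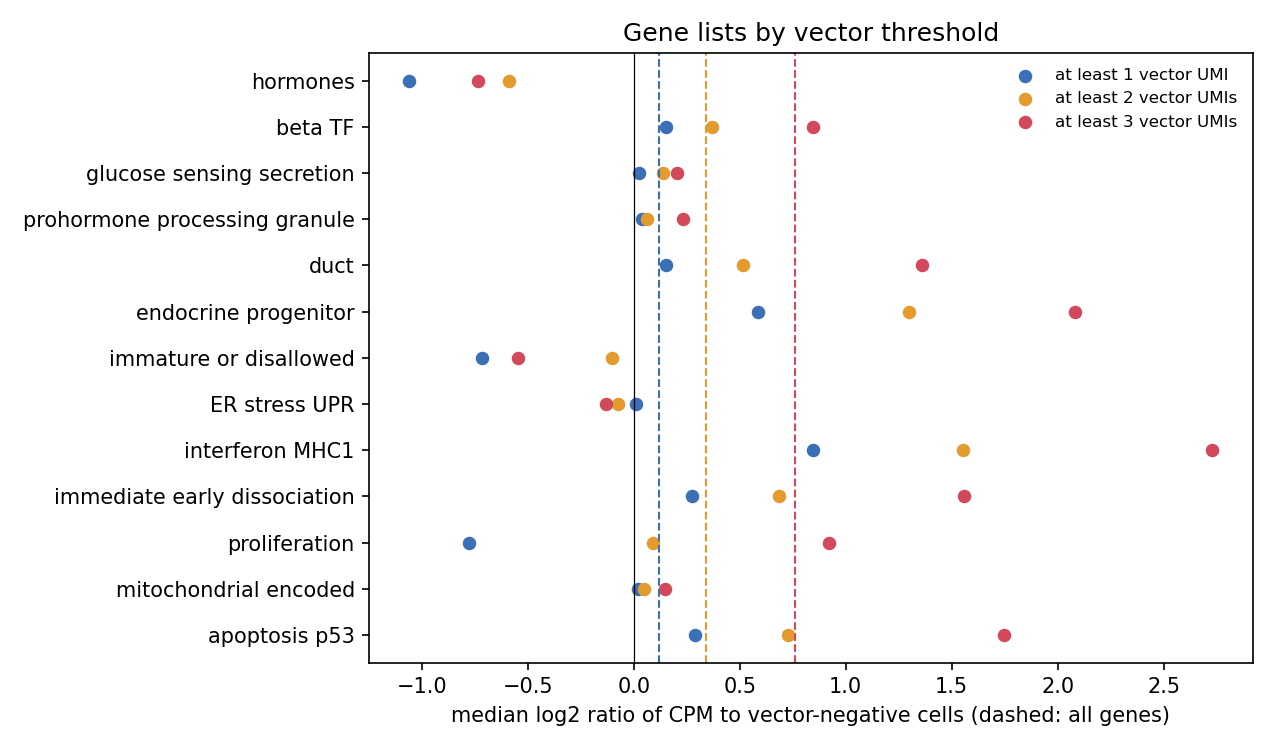
Median log2 ratio of CPM for each of 13 gene lists, for cells with at least 1, 2 or 3 vector UMIs against cells with 0, 1 point per list and threshold. Dashed lines mark the median of all genes (0.12, 0.34 and 0.76); the interferon list reaches 2.73 and the glucose sensing list 0.20 at 3 vector UMIs.

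In 2 lists the direction depended on the 3 cells with markers of other types and on how the classes were drawn. The proliferation list had a median of -0.78 with 8 of 10 members lower, and the list of immature or disallowed β-cell genes -0.72 with 5 of 7 lower. Without those cells the medians were 0.23 and 0.34. With them kept, the proliferation median was 0.090 with at least 2 vector UMIs and 0.92 with at least 3, and the immature median 0.0060 against vector-negative cells from the median depth up. Top2a had 1 UMI in vector-positive and 23 in vector-negative cells, and 1 against 1 without the 3 cells. Ratios without them were 1.30 (0.547 to 2.89) for Ldha, 1.17 (0.195 to 5.13) for both Cdk1 and Ube2c, 1.47 (0.497 to 3.97) for Birc5 and 0.342 (0.00770 to 2.55) for Mki67, all within counting error of 1. With them the ratios were 0.393, 0.393, 0.330, 0.458 and 0.145. The DNA replication genes Pcna (0.967), Mcm2 (0.917) and Tyms (1.13) were near 1, and cyclin Ccnb1 was at 2.54 (1.06 to 6.03), with 9 of its 12 vector-positive UMIs in 1 cell. Among the disallowed genes Cat (0.478, 0.120 to 1.40), Zfp36l1 (0.4999, 0.125 to 1.47) and Oat (1.09, 0.698 to 1.65) were within counting error of 1. Npy was at 1.53 (1.14 to 2.05), with 52.7% of its vector-positive UMIs in 1 cell.

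Shares of cells with a UMI at equal depth differed for Mafa, Onecut2, Nkx6-2, B2m and Gal. After thinning, Mafa was seen in 19.5% (12.8 to 27.8) of 118 vector-positive cells and in 0 of 333 vector-negative cells (up to 1.10%). Onecut2 was seen in 19.5% (12.8 to 27.8) and 3.90% (2.09 to 6.58), Nkx6-2 in 16.1% (9.98 to 24.0) and 2.40% (1.04 to 4.68), and B2m in 55.9% (46.5 to 65.1) and 39.6% (34.3 to 45.1). Gal was seen in 23.7% (16.4 to 32.4) and 12.01% (8.72 to 16.0). Ucn3 (81.4% and 77.2%), Gip (96.6% and 97.6%) and Krt19 (1.69% and 2.10%) had overlapping intervals. Gcg was seen in all 451 thinned cells, so a UMI of an abundant hormone gene did not mark its cell type. Unthinned, the shares were 23.9% and 1.91% for Mafa, 34.3% and 9.81% for Onecut2, 23.1% and 6.54% for Nkx6-2 and 88.8% and 74.1% for B2m.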

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

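The class threshold of at least 3 vector UMIs, the settings by cluster, those without the 3 cells, the joint setting, the single vector features, cluster levels with insulin out of the total and hormones without their top cell in each class were chosen after seeing the data. Values that answer a comparison were the same within their interval in 123 cases, moved in 95 and reversed in 27, and values of named genes were the same in 846, moved in 516 and reversed in 56. List and gene values below are log2 ratios, and the cause of each move was not tested. No paired analysis was possible because 1 pooled library gives no pairs. The filter removed 0 cells, so using no cell filter and keeping all cells that pass the filter gave the same values by construction. The same cases counted above include 1 and 14 such values for comparisons and 95 for named genes. The comparison within β-like clusters could not be run since no cluster could be named β-like. The stricter filter, list members from 5 UMIs and the 2 lists without the vector's genes gave values within the main intervals. The other clusterings gave 8 and 6 clusters, in which the cluster matching cluster 2 was 65.8% and 64.9% vector-positive. The share of vector-positive cells was 9.58% from 2 UMIs, 11.8% after thinning, 13.8% with adeno-Mafa_3Prime alone and 17.96% with ad5_F and ad5-rc alone. Without thinning, the vector-positive shares were 99.3% (Gip), 50% (Gal), 88.8% (B2m) and 34.3% (Onecut2), and the vector-negative shares 40.3% (Gal), 74.1% (B2m), 5.18% (Krt19), 2.72% (Sox9), 1.91% (Mafa), 88.6% (Ucn3), 9.81% (Onecut2) and 6.54% (Nkx6-2).

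Settings fixed in advance moved these values. With a class of at least 2 vector UMIs, insulin was at -0.18. List medians were -0.59 (hormones), 0.37 (β-cell factors), 0.14 (glucose sensing), 0.52 (duct), 1.30 (progenitor), -0.10 (immature or disallowed), -0.074 (ER stress), 1.56 (interferon), 0.69 (immediate early) and 0.73 (p53). Medians reversed to 0.090 (proliferation). With vector-negative cells only from the median depth up, insulin was at -0.11. List medians were -0.093 (hormones), 0.31 (β-cell factors), 0.14 (prohormone processing), 1.08 (progenitor), 1.12 (interferon), 0.46 (immediate early) and -0.13 (proliferation). Medians reversed to 0.0060 (immature or disallowed). Genes reversed to 1.04 (Gcg), 0.49 (Sst), 0.093 (Ppy) and 0.015 (Anxa2). With every cell weighted equally, insulin was at -0.095. List medians were -1.53 (hormones), 0.33 (β-cell factors), 0.12 (glucose sensing), 0.38 (duct), 1.03 (progenitor), -1.13 (immature or disallowed), 1.06 (interferon) and 0.58 (immediate early). With doublets left out, insulin was at -0.038. With insulin, Iapp and mitochondrial genes out of the total, list medians were -1.42 (hormones), 0.070 (β-cell factors), -0.059 (glucose sensing), -0.045 (prohormone processing) and -0.072 (ER stress).

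The added settings gave the following. With a class of at least 3 vector UMIs, insulin was at -0.57. List medians were -0.74 (hormones), 0.84 (β-cell factors), 0.20 (glucose sensing), 0.23 (prohormone processing), 1.36 (duct), 2.08 (progenitor), -0.13 (ER stress), 2.73 (interferon), 1.56 (immediate early), 0.15 (mitochondrial) and 1.75 (p53). Medians reversed to 0.92 (proliferation). Genes reversed to 0.80 (Sst), 0.73 (Gemin8), 0.053 (Zfp442) and 0.43 (Anxa2). With at least 3 vector UMIs and insulin, Iapp and mitochondrial genes out of the total, list medians were -0.46 (glucose sensing), -0.43 (prohormone processing), 0.70 (duct), 1.42 (progenitor), -1.21 (immature or disallowed), -0.79 (ER stress), 2.07 (interferon), 0.90 (immediate early) and 1.09 (p53). Medians reversed to 0.26 (proliferation). Genes reversed to 0.15 (Sst) and 0.071 (Gemin8). With only the 3 cells left out, insulin was at -0.051. Medians reversed to 0.34 (immature or disallowed) and 0.23 (proliferation). Genes reversed to 0.89 (Anxa2), 0.42 (Ldha), 0.063 (Ifitm3) and 1.45 (Top2a). With cluster 1 left out, insulin was at -0.076. List medians were -0.087 (hormones) and 0.094 (prohormone processing). Genes reversed to 0.080 (Gcg) and 0.74 (Sst). With cluster 2 left out, insulin was at 0.029, reversed. List medians were -1.30 (hormones), -0.036 (prohormone processing) and 0.20 (interferon). Medians reversed to -0.069 (β-cell factors), -0.14 (duct), -0.23 (progenitor), -0.26 (immediate early), 0.065 (proliferation) and -0.14 (p53). Genes reversed to -0.076 (Cd9), -0.097 (Clu), 0.71 (Anxa2), -0.21 (Sox4), -0.48 (Npy), 0.20 (Ldha), -0.018 (Ifi27), 1.65 (Top2a) and -0.22 (Cdkn1a).

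With cluster 0 alone, insulin was at -6.8e-05. List medians were -0.0077 (hormones), 0.12 (progenitor) and 0.23 (interferon). Medians reversed to -0.048 (β-cell factors), -0.0025 (duct), 0.081 (immature or disallowed), -0.19 (immediate early), 0.031 (proliferation) and -0.11 (p53). Genes reversed to 0.11 (Gcg), 0.053 (Sst), -0.27 (Endou), -0.20 (Rprml), -0.49 (Cd9), 0.94 (Anxa2), -0.10 (Sox4), -0.53 (Npy), 0.27 (Ldha), 1.57 (Top2a) and -0.63 (Cdkn1a). With cluster 2 alone, insulin was at 0.45, reversed. List medians were 0.25 (glucose sensing), 0.24 (prohormone processing), -3.23 (immature or disallowed), -0.054 (ER stress), -4.60 (proliferation), -0.45 (mitochondrial) and 0.079 (p53). Medians reversed to 0.35 (hormones), -0.57 (duct) and -0.54 (interferon). Genes reversed to 0.23 (Gcg), 2.82 (Sst), 0.99 (Ppy), -0.13 (Onecut2), -0.15 (Clic6), -0.043 (B2m), -0.50 (Ifit1), -0.54 (Oasl2) and -0.90 (Ccnb1). With cluster 2 alone and without the 3 cells, insulin was at 0.14, reversed. List medians were -0.046 (glucose sensing), -0.11 (prohormone processing), -0.14 (ER stress), 0.28 (interferon), 0.47 (immediate early) and -0.34 (mitochondrial). Medians reversed to 0.13 (hormones), -0.19 (β-cell factors) and -0.017 (duct). Genes reversed to 0.13 (Gcg), 2.74 (Sst), 0.77 (Ppy), -0.14 (Onecut2), -0.34 (Clic6), 0.17 (Sec22c), 0.17 (Zfp442), 0.91 (Anxa2), -0.23 (Sox4), 0.46 (Ifitm3) and -0.39 (Ifit1).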

Other observations

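All tests in this part were chosen after the results had been seen. Gip RNA in cluster 2 came mostly from a few cells. Gip encodes the incretin made by K cells of the gut. Of the 70 cells of cluster 2 without markers of other types, 13 held at least 10000 CPM of Gip (10148 to 178151) and 10 of these were vector-positive. The other cells had a median of 532 CPM, near the 427 CPM of cluster 0, and 1 cell outside cluster 2 passed 10000 CPM. The somatostatin of cluster 2 also came from few cells: 1 held 1308 Sst UMIs and the next 15.

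Vector UMIs in 79 cells of cluster 0 were weighed first. Free vector RNA at 1 rate per UMI could give the counts, since 14 cells with at least 2 vector UMIs were seen against 11.5 expected (99% range 5 to 18). Vector RNA made by the cells themselves at 1 rate per UMI would give the same range, so the test cannot tell the 2 apart. The test also did not use egfp. The median cell held 18213 CPM of egfp among the 86 cells with 1 vector UMI and 7477 CPM among vector-negative cells. Over cluster 0 the median was 9989 CPM. The first 2 sets span the clusters, so these values do not settle the source in cluster 0. Doublets of both clusters are excluded as the source in most of these cells. The 9 leading genes of cluster 2 had a median ratio of 1.05 between vector-positive and vector-negative cells of cluster 0. A mix in every cell would give 8.17. The ratio is pooled over the 79 cells, so doublets in a few of them are not excluded. Low uptake by these cells stays open, as the rate of cluster 0 was 1.25 times that of cluster 1 (0.610 to 2.99). Cluster 1 also held insulin-rich cells (Ins1 at 166035 CPM over the cluster), so it does not stand for other cell types alone. A single vector UMI in a deep cell may therefore not mark a cell that took up the vector, while at the rate of cluster 0 only 8.09% of cluster 2 cells would hold a vector UMI. That share rests on a rate per UMI. If free RNA instead adds a fixed number of UMIs per droplet, the share to compare is the 22.2% of cluster 0. Vector UMIs were seen in 68.6% of the 70 cells of cluster 2.

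Insulin and GFP RNA in cluster 2 could come from β-cells by way of the droplets. Free RNA is excluded as the whole source of the insulin RNA in most of the cells. The lower quartile of insulin UMIs per cell was 2025, and the highest of 28 Gcg-rich cells of similar depth held 1443. Of the 70 cells, 61 were above that value. An exception is the duct-marker cell, which held 2275 insulin UMIs among its 52316. If these are free RNA, free RNA can exceed the lower quartile of 2025. It would still lie under the median of 3551.5 insulin UMIs in the 70 cells. The test did not cover egfp, which stood at 6.60 per 100 insulin UMIs in the 70 cells and 2.66 in the Gcg-rich cells. Doublets with a cell of cluster 0 above its lower quartile of 29566 UMIs are excluded by depth. The median was 11211 UMIs, and 0 of 70 cells reached that quartile. Cells of cluster 0 went down to 6911 UMIs, so doublets with its shallowest cells are not excluded. No biological explanation was tested, since the labels give no group for these cells.

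Last, the higher class I and interferon genes in cells with at least 3 vector UMIs were weighed. The smaller insulin share is excluded as the whole cause. With insulin, Iapp and mitochondrial genes out of the total, the list median fell from 2.73 to 2.07 (1.56 to 2.27). The median of all genes fell from 0.76 to 0.10. Macrophage or NK RNA is excluded as the whole source only if such cells hold these markers about as richly as B2m: the 17 of 19 markers rare in vector-negative cells summed to 41.1 CPM (23.5 to 66.7), against the 840 CPM by which B2m was higher, and Lyz2, Tyrobp and Ptprc gave 0 UMIs. The cut for a rare marker and the bound were set once the counts were known, and Cd68 was higher (12 against 9 UMIs, 42.9-fold, 16.6 to 115, 75.0% in 1 cell), with Cd74 at 2.41 (0.477 to 7.57). Presence of the vector itself stays open, because within cluster 2 vector-positive cells stood 0.28 (-0.0058 to 0.57) above vector-negative ones, while the latter stood 2.61 (2.19 to 3.06) above cluster 0, or 1.67 with insulin out of the total. At the mean vector rate of cluster 2, 10.5% of its cells would show no vector UMI against 31.4% seen, so sampling may account for some of the vector-negative cells there but not for all at that rate.

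A hypothesis for the Gip cells is a wider enteroendocrine programme, and a second is a hepatobiliary one, from leading genes such as Ambp. Both lists were written after Gip had been seen, and the enteroendocrine list shares 4 of 15 members with lists used above. The lists were first tried on all cells with at least 3 vector UMIs against those with 0, where 7 of 9 measured enteroendocrine members were higher (median 1.25, 99.1st percentile) and the hepatobiliary list lay at the 43.0th percentile. Those cells were not chosen by Gip, so the 13 Gip-rich cells were then set against the other 57 cells of cluster 2, at median depths of 11117 and 11280 UMIs. Of 8 measured enteroendocrine members 3 were higher, with a median log2 ratio of -0.24 (-0.60 to 0.083) at the 7.94th percentile of matched lists, and -0.14 without the shared members. The list was not higher in the Gip-rich cells than in the other cells of cluster 2. The interval leaves no room for a rise of its median beyond 0.083. A programme shared by the other cells of cluster 2 would not show in this comparison, so the hypothesis stays open to that extent. The fatty acid receptor gene Ffar4 had a ratio of 3.32 (1.38 to 7.73), while Chgb (0.797, 0.737 to 0.860) and Etv1 (0.360, 0.141 to 0.773) were lower. The gut hormone gene Sct was at 3.23 (0.809 to 11.8), with 4 of its 5 UMIs in 1 cell, and Cck, Ghrl, Nts and Tac1 gave 0 UMIs in the Gip-rich cells. Of the 12 hepatobiliary members 0 had enough UMIs, so that list could not be tested there.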
